A study of Mus musculus with 12 samples.

How the data were processed

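RNA was sequenced from 12 cultures of intrahepatic cholangiocyte organoids, which are balls of bile duct epithelium grown in a basement membrane gel. Per the labels' protocols, 6 mice each gave 1 culture from the hilum of the liver and 1 from its periphery, and RNA was taken at passage 5. The mice were 3 Jag1 wild-type animals (WT; mice 1221, 1223 and 1225) and 3 animals homozygous for the Ndr allele (Jag1 Ndr/Ndr; mice 1224, 1220 and 1219). The 4 groups of genotype and region therefore held 3 libraries each, from 3 mice.

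The authors deposited a table of raw read counts per gene, with 53700 gene identifiers and 1 column per library, and reads were assigned to genes with featureCounts on GRCm39, per the submitters' processing notes. The aligner, the annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. Counts of overlapping genes and of near-identical family members, such as the Gsta, Gstm, Reg3 and Serpinb9 genes, are uncertain for that reason. The authors also deposited a table of normalized values (signal), and DESeq2 1.34.0 was used, per the submitters' processing notes. Tested on its values, that signal table held whole counts divided by 1 size factor per library: 100% of the values came out whole within a tolerance of 0.01. These recovered whole counts equalled the raw count in 43.1% of cells. A rerun of ComBat-seq (sva 3.50.0) on the raw counts, with derivation date as the batch and genotype as the group to keep, gave the recovered count in 99.4% of cells, against 44.8% when no group was kept. No header or label records such a step.

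All main results start from the deposited raw counts. They summed to 6708822 to 16030880 per library, and 28444 genes had at least 1 count. Gene symbols came from a GENCODE M21 table on GRCm38, used for names only, which matched 52093 identifiers and left 1607 without a name; 28 of the 15014 tested genes had no symbol. Of 792 gene list symbols, 788 matched an identifier, older symbols included.

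Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM normalization, robust quasi-likelihood F test). A fit over all 12 libraries had 1 coefficient per group and 8 residual degrees of freedom, and 15014 genes were tested. From it came the genotype effects in hilar and in peripheral organoids, the region effects (hilar minus peripheral) in WT and in Ndr organoids and over both genotypes, and the interaction. The genotype effect over both regions came from the 6 mouse totals, in which the pair of libraries from a mouse was summed (15401 genes, 4 residual degrees of freedom). Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Expression is given as CPM (the cpm function of edgeR, on TMM-scaled library sizes), as mean ± SD of n = 3 cultures, or of n = 3 mouse totals for the summed comparison. Standard errors of log2 fold changes were computed back from the fold and its F statistic. An exact permutation test of 3 mice against 3 cannot give a two-sided p under 0.1, so all p-values come from the models named.

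There were 28 gene lists: Notch components, Notch targets, cholangiocyte identity, biliary transport, hepatocyte, large-duct and mucous, IGF and insulin, proliferation, Wnt and stem, YAP targets, TGF-beta and mesenchymal, basement membrane, junction and polarity, primary cilium, inflammation, interferon, cholesterol synthesis, hypoxia and glycolysis, unfolded protein response, xenobiotic and antioxidant, immediate early and heat shock, mitochondrially encoded, sex-linked, and 5 lists of other cell types (fibroblast and stellate, endothelial, immune, mesothelial and neural, gut and pancreas). Lists with at least 5 tested members were tested against the other genes with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. fry was run as well, which does not compare a list with other genes. List p-values were adjusted by Benjamini-Hochberg over the lists of a comparison. Members were also adjusted over the list alone. That adjustment was made within each list and comparison, with no correction over lists or comparisons, so some members would pass by chance.

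The comparisons, the lists and the main alternatives were fixed before the data were examined, as was the rule for naming genes. That rule names Jag1 in each comparison, genes past the threshold by size of change, and, where fewer than 10 pass, the 10 genes with the smallest p among named genes of at least 5 CPM in the higher group. It also names up to 4 members of a list past the threshold or, where none passes, its 2 most abundant members, as values. Genes past 0.05 only when adjusted over the list alone are named outside that rule and were chosen after their values were seen, as were single members mentioned for their level in 1 library.

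Hilar and peripheral cultures with the same mouse number come from the same animal, so the numbers pair the libraries. The correlation of the pair's deviations from the group means was 0.14, -0.34 and -0.31 in mice 1224, 1220 and 1219, and 0.33, 0.45 and -0.062 in mice 1221, 1225 and 1223. Fits with the mouse as a block are printed beside a result where they change a call.

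Derivation dates differed between the genotypes. Mice 1221 and 1223 were processed on day 15 of June, 1225 and 1224 on day 21, 1220 on day 18 and 1219 on day 17, so that 1 date held mice of both genotypes. No pair of libraries was identical, and Spearman correlations ran from 0.908 to 0.975 within groups and from 0.871 to 0.978 between groups.

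The steps were tested on simulated counts with known changes drawn from the real means. Changed genes were taken from those averaging at least 5 CPM, so recovery of less abundant genes was not tested. For the hilar genotype comparison (14799 genes), edgeR recovered 10.3%, 64% and 89.6% of genes changed by a fold of 2, 4 and 8, and 2.56% of its calls were false. For the same comparison DESeq2 recovered 27.6%, 84% and 95.5%, and 23.9% of its calls were false. For the mouse totals, edgeR recovered 24.1%, 89.3% and 98.5% with 5.77% false calls among 14944 genes, and DESeq2 recovered 67.2%, 96% and 100% with 25.2% false calls. For the region effect in Ndr organoids, edgeR with the mouse block recovered 3.45%, 50.7% and 86.6% with 7.55% false calls. camera, with either correlation, and fry called the simulated changed list and 0 of 100 unchanged lists. All these counts were simulated without correlation between genes, and without a mouse effect for the block to take up. They therefore do not test how often camera with the preset correlation calls unchanged lists whose members vary together. In the fit with the mouse as a block, estimated correlations of the real lists ran from -0.0136 for cholangiocyte identity to 0.839 for proliferation genes.

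Alternatives were DESeq2 1.42.0, limma-voom, other normalizations and filters, pairwise fits, blocks, derivation date or day as a covariate, the normalized signal table on a log2 scale with a pseudocount of 1, and leaving out each library or mouse in turn.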

Results

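Alagille syndrome is an inherited disorder of the bile ducts that arises mostly from mutations in JAG1, which encodes a ligand of the Notch pathway. The Ndr allele of mouse Jag1 is a missense change in this ligand. Organoids of bile duct epithelium were grown from the hilum and from the periphery of livers of 3 WT and 3 Jag1 Ndr/Ndr mice, and the design asks which genes differ by genotype, by region, and by genotype in only 1 region. Each of the 4 groups held 3 cultures. WT hilar libraries held 16030880, 7838852 and 6708822 counts (mice 1221, 1225 and 1223) and WT peripheral libraries 12356642, 9521405 and 8405443. Ndr hilar libraries held 7434735, 7129887 and 10462220 counts (mice 1224, 1220 and 1219) and Ndr peripheral libraries 11494954, 10440938 and 10130491. All libraries carried Y-linked transcripts, with Ddx3y (ENSMUSG00000069045) at group means from 71.3 to 93.2 CPM, and at most 1 Xist read.

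Genes of bile duct epithelium were abundant in the cultures, among them Spp1 and Krt18, the most abundant members of the cholangiocyte identity list. Clu, a secreted chaperone counted here with the large-duct and YAP lists, averaged between 11900 and 20700 CPM per group. Trf, of the hepatocyte list, was abundant as well, at 3320 ± 1810 CPM in WT and 1730 ± 646 CPM in Ndr mouse totals. Identity was not tested against other cell types. Spp1, which encodes osteopontin, averaged 4040 ± 2830 CPM in WT hilar and 7360 ± 957 CPM in Ndr hilar cultures, and 5470 ± 2490 and 3890 ± 3800 CPM in the peripheral ones. Krt18 lay between 1720 and 3400 CPM in the 4 groups. The 30 tested biliary identity genes had median log2 differences between genotypes of 0.07 in hilar and -0.08 in peripheral organoids, with camera adjusted p of 0.947 and 0.4. The mean difference of this list had the other sign in each region, -0.12 and 0.00. The first 2 principal components carried 30.2% and 16.5% of the variance, and neither separated the 4 groups, though the 3 Ndr hilar libraries lay above the 3 Ndr peripheral ones on the first. Genotype accounted for 11.6% of the variance over genes, region for 10.7% and their interaction for 9.36%, where each would take 9.09% by chance.

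**Figure D1:**
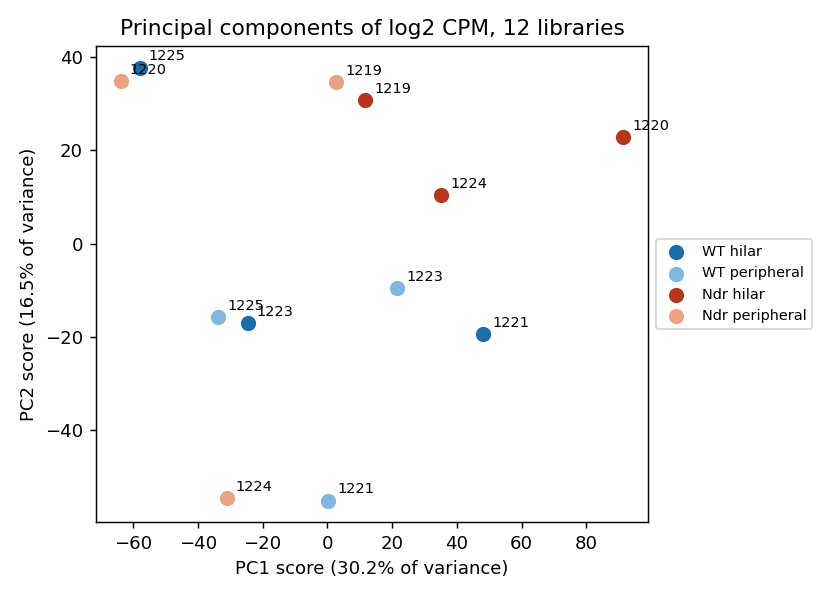
Scores of the 12 libraries on the principal components that carry 30.2% and 16.5% of the variance of log2 CPM. Points are libraries, coloured by group and marked with the mouse number.

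Jag1 itself was expressed at a like level in both genotypes. The Ndr change leaves the transcript in place, so its level does not test the labels. Mouse totals of Jag1 (ENSMUSG00000027276) averaged 129 ± 30.4 CPM in WT and 115 ± 12.5 CPM in Ndr mice (n = 3 each; log2 -0.17, SE 0.198, edgeR adjusted p = 0.926). In hilar cultures Jag1 averaged 120 ± 59.3 CPM in WT and 141 ± 53.3 CPM in Ndr, and in peripheral cultures 128 ± 44.9 and 103 ± 44.8 CPM. The log2 difference between genotypes was 0.24 (SE 0.431) in hilar and -0.31 (SE 0.432) in peripheral cultures, below 1 SE in both. The log2 difference between hilar and peripheral cultures was -0.09 in WT and 0.46 in Ndr, 0.18 over both genotypes, and the interaction was 0.55 (SE 0.61).

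Across both regions, Rgs16, a brake on G-protein signalling, Inhba, the activin A subunit, and Tnc, the matrix protein tenascin C, were among the genes with the smallest p between genotypes, at lower values in each Ndr mouse than in each WT mouse. Adgrg7, an adhesion receptor, and Serpinb9, a granzyme inhibitor, were higher in each Ndr mouse. All these genes were chosen by p in the same mice, so the separation is no further support. By chance 10% of genes would separate 3 mice from 3. edgeR called 0 of 15401 genes in the mouse totals at an adjusted p under 0.05, with 834 genes at an unadjusted p under 0.05 (5.42%, where 5% is the chance share) and a median SE of 0.222. Without Ndr mouse 1224 that count was 1450, without 1220 it was 483, and edgeR called 4 genes without 1219. limma-voom called 0 genes and DESeq2 called 124, of which 53 were higher and 71 lower in Ndr mice. By unadjusted rank, Rgs16 (ENSMUSG00000026475) came first, at 80.3 ± 11.2 CPM in WT and 10.8 ± 3.53 CPM in Ndr mice (n = 3 each; log2 -2.89, SE 0.252, edgeR adjusted p = 0.124). Inhba (ENSMUSG00000041324) averaged 53.9 ± 9.05 and 13.4 ± 3.35 CPM (log2 -2.01, SE 0.232), Tnc (ENSMUSG00000028364) 33 ± 7.63 and 3.46 ± 1.56 CPM (log2 -3.25, SE 0.4), and Akap12 (ENSMUSG00000038587), a kinase scaffold, 55.5 ± 13.3 and 14.2 ± 4.28 CPM (log2 -1.97). Adgrg7 (ENSMUSG00000022755) averaged 51.3 ± 27.5 CPM in WT and 391 ± 86.1 CPM in Ndr mice (log2 2.93, SE 0.408), and Serpinb9 (ENSMUSG00000045827) 56.2 ± 19.2 and 200 ± 40.4 CPM (log2 1.83). Soga3, Dclk1, Eif3j1 and Dock11, at log2 differences of -3.65, -0.97, -0.91 and -0.98, completed the 10 named genes of at least 5 CPM with the smallest p. All 10 lay between edgeR adjusted p of 0.124 and 0.277 and past the DESeq2 threshold.

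Among the gene lists, xenobiotic and antioxidant genes stood higher and inflammation genes lower in Ndr mice. The 28 tested xenobiotic and antioxidant genes had a median log2 difference of 0.48, with 22 of them positive (camera adjusted p = 7.96e-07, and adjusted p = 0.554 with an estimated correlation). When adjusted over the list alone, 5 of its members passed in the edgeR test of mouse totals. These were Nqo1 (0.565 ± 0.332 CPM in WT and 4.25 ± 0.617 CPM in Ndr mice), Aldh1a1 (10.6 ± 4.42 and 31.7 ± 4.74 CPM), Gstm1 (42.8 ± 7.86 and 75.5 ± 3.49 CPM), Gsta3 (184 ± 30.2 and 304 ± 23 CPM) and Gstp1 (88.2 ± 19.1 and 148 ± 16.2 CPM). The 37 inflammation genes had a median of -0.50, with 28 negative (camera adjusted p = 7.96e-07, and adjusted p = 0.554 with an estimated correlation). Cxcl2, a chemokine, passed when adjusted over the list alone, at 34.7 ± 6.53 CPM in WT and 15.8 ± 0.775 CPM in Ndr mice, while of the most abundant members Lcn2 averaged 4040 ± 1950 and 2190 ± 839 CPM, and Cp 3520 ± 2090 and 1940 ± 130 CPM. Both lists stayed called by camera when each mouse was left out in turn, but the inflammation median changed sign in limma-trend on the normalized signal table. Basement membrane genes (median -0.24) and unfolded protein response genes (median -0.27) were lower by camera at adjusted p of 0.00461 and 0.00763, with an adjusted p = 0.662 and an adjusted p = 0.66 with an estimated correlation. Neither stayed called without Ndr mouse 1220 (camera adjusted p of 0.252 and 0.0731) or WT mouse 1225 (0.0728 and 0.055), nor the unfolded protein list without WT mouse 1223 (0.106).

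Single large-duct and mucous genes passed in both directions between the genotypes in edgeR, but only when adjusted over the list alone. Of the 22 tested members, 9 passed in edgeR that way, at edgeR adjusted p over all genes from 0.453 to 0.869. The list as a whole had a median of -0.14, a mean of 0.45 and a camera direction upward (camera adjusted p = 0.873). Foxa3, a transcription factor of endoderm, averaged 7.96 ± 1.51 CPM in WT and 16.4 ± 1.21 CPM in Ndr mice. The galectin genes Lgals4 (107 ± 44.7 and 491 ± 329 CPM) and Lgals2 (9.15 ± 5.45 and 80.5 ± 71.3 CPM) and the antimicrobial lectin genes Reg3b (14.9 ± 12.9 and 507 ± 683 CPM) and Reg3g (3.84 ± 3.13 and 93.2 ± 127 CPM) were also among the 9. Muc20 (26.6 ± 14.9 and 8.04 ± 2.28 CPM), Pigr (16.7 ± 15.3 and 2.4 ± 0.848 CPM), Sox17 (2.06 ± 0.909 and 0.509 ± 0.264 CPM) and Muc5b (7.25 ± 10.3 and 0.143 ± 0.248 CPM) went the other way. Reg3b and Reg3g reached 1294 and 240 CPM in Ndr mouse 1219, against at most 156.4 and 22.51 CPM in the other Ndr mice. Muc5b reached 19.11 CPM in WT mouse 1221 and at most 1.69 CPM in the other WT mice. fry for changes in either direction gave adjusted p of 0.00926 for this list, 0.00926 for the TGF-beta and mesenchymal list and 0.0133 for the xenobiotic and antioxidant list. In the TGF-beta and mesenchymal list, Inhba, Tnc and Sparc (0.419 ± 0.252 CPM in WT and 1.99 ± 0.537 CPM in Ndr mice) passed when adjusted over the list alone. Single members of other lists did as well. Ttr, the transthyretin gene, averaged 3.55 ± 2.13 and 24.3 ± 1.47 CPM, Lgr4, a receptor for R-spondins, 66.8 ± 14 and 119 ± 5.3 CPM, and Irs1, an insulin receptor substrate, 24 ± 3.44 and 12.4 ± 2.36 CPM. Wt1 had no count in any of the 6 WT libraries and 6.33 ± 8.21 CPM in Ndr mice, so that no fold is given.

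**Figure D2:**
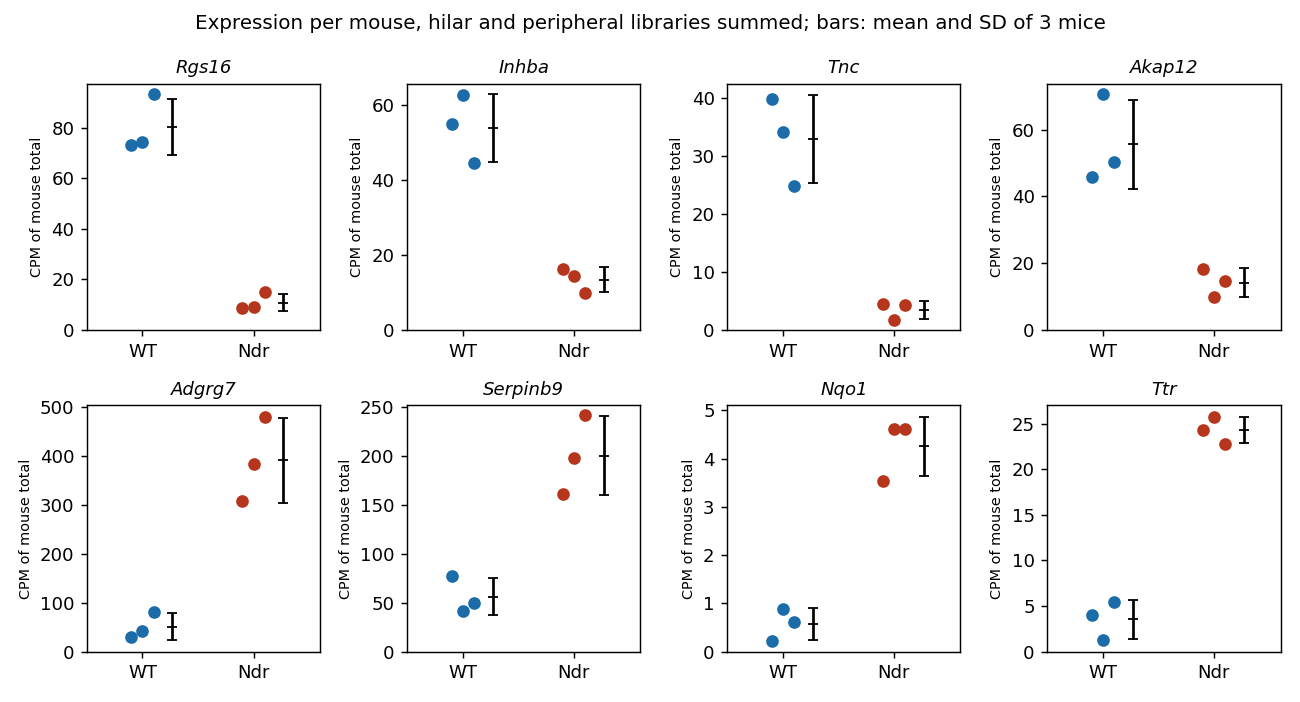
Expression of 8 genes in CPM of the mouse total, with hilar and peripheral libraries summed. Points are mice, and bars give the mean and SD of 3 WT and 3 Ndr mice; Rgs16 ran from 73.2 to 93.2 CPM in WT and from 8.52 to 14.9 CPM in Ndr mice.

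In hilar organoids, which come from the large ducts near the liver's entry, Syne1, Dock11, Adgrg7 and Inhba had the smallest p between genotypes among named genes of at least 5 CPM. Proliferation genes were lower, and primary cilium genes higher, in Ndr than in WT hilar organoids by camera with the preset correlation, each at an adjusted p = 0.805 with an estimated correlation, and the proliferation median of -1.71 was -0.306 without WT hilar 1225. edgeR called 0 of 15014 genes, with 982 at an unadjusted p under 0.05 (6.54%) and a smallest adjusted p of 0.715. That count was 1985 without WT hilar 1221, 514 without Ndr hilar 1220 and 518 without WT hilar 1225. limma-voom called 0 and DESeq2 called 44, of which 14 were higher and 30 lower. By unadjusted rank, Syne1 (ENSMUSG00000096054), a nuclear envelope protein gene, averaged 34.3 ± 13.8 CPM in WT and 4.22 ± 2.93 CPM in Ndr hilar cultures (n = 3 each; log2 -3.03, SE 0.518, edgeR adjusted p = 0.715). Dock11 (ENSMUSG00000031093) averaged 63 ± 21.1 and 16 ± 6.6 CPM (log2 -1.97, SE 0.343), Adgrg7 23.7 ± 12.8 and 467 ± 259 CPM (log2 4.30, SE 0.763), Inhba 50.7 ± 15 and 6.91 ± 4.58 CPM (log2 -2.86), and Lgr4 (ENSMUSG00000050199) 63.2 ± 13.2 and 148 ± 22.1 CPM (log2 1.23). Fgf13, Smox, Inpp4b, Antxr2 and Polr1b followed, all lower in Ndr cultures, at log2 differences of -2.96, -1.78, -4.39, -1.55 and -1.05. All 10 passed in DESeq2. When adjusted over the list alone, Inhba, Sparc and Tnc of the TGF-beta and mesenchymal list, Lgr4 and Lgr6 of the Wnt and stem list, and Ttr (4.91 ± 2.86 and 42.8 ± 15.4 CPM) of the hepatocyte list passed in edgeR.

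camera called 8 lists in hilar organoids, each at an adjusted p = 0.805 with an estimated correlation. All 44 proliferation genes were lower in Ndr cultures, with a median log2 difference of -1.71 (camera adjusted p = 2.19e-13). Top2a averaged 233 ± 238 CPM in WT and 67.1 ± 19.7 CPM in Ndr hilar cultures, and Mcm6 147 ± 105 and 99.7 ± 9.4 CPM. WT hilar culture 1225 alone was high in this list, and without it the median was -0.306. Primary cilium genes had a median of 0.27, with 33 of 37 positive (camera adjusted p = 9.89e-05). The 5 tested members of the fibroblast and stellate list had a median of 1.23 (camera adjusted p = 0.00327), and most of that list was too low to be tested. These 3 lists stayed called by camera when each library was left out in turn. Hypoxia and glycolysis genes (median -0.63, camera adjusted p = 3.81e-05) were not called without Ndr hilar 1220 (0.125), inflammation genes (median -0.88, 6.16e-05) without WT hilar 1223 (0.0806, median -0.20), cholesterol synthesis genes (median -0.53, 0.000409) without WT hilar 1225 (0.637, where the cholesterol_synthesis median turned to 0.024), and mitochondrially encoded genes (median 0.86, 0.00145) without Ndr hilar 1224 (0.1). Basement membrane genes (median -0.57, camera adjusted p = 0.0344) were not called without Ndr hilar 1219 (0.873) or WT hilar 1221 (0.167).

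**Figure D3:**
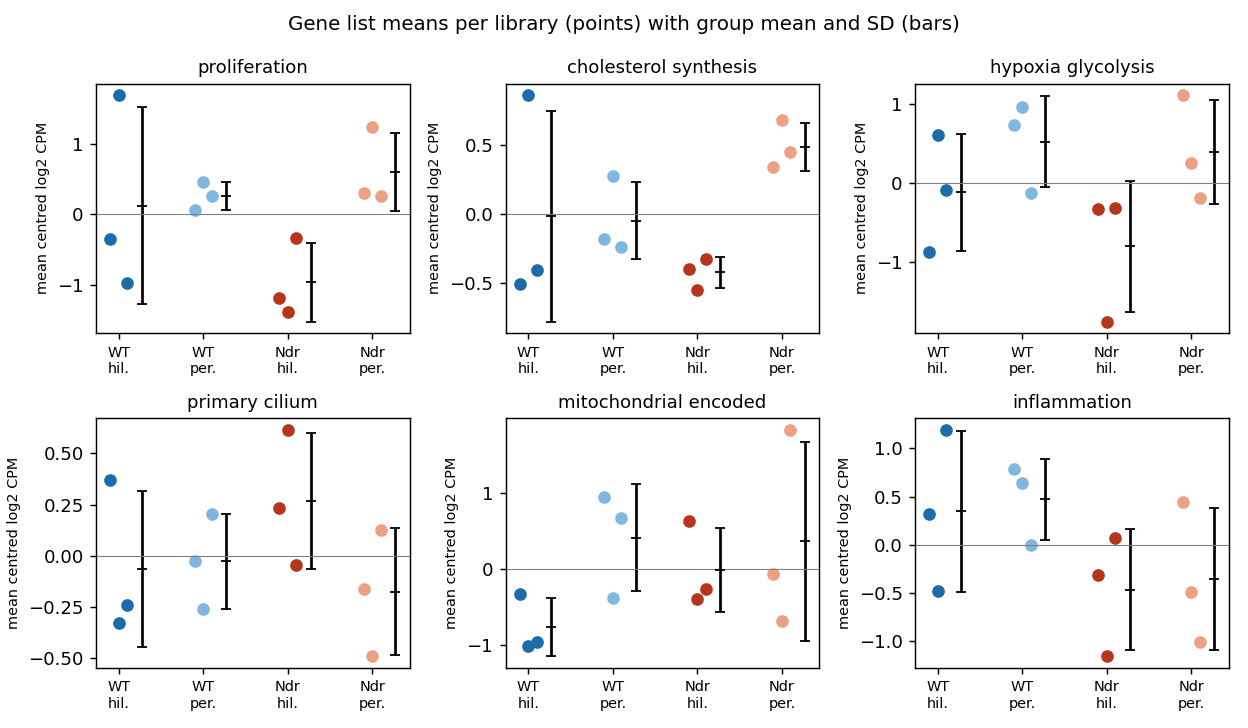
Mean log2 CPM of the members of 6 gene lists, centred on the mean of all libraries, in the 4 groups. Points are cultures, and bars give the mean and SD of 3; proliferation runs from -0.981 to 1.69 in WT hilar cultures, the widest group in that panel.

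In peripheral organoids, from the small ducts, Rgs16, the protease inhibitor gene Slpi and the guidance cue gene Ntn1 were lower in Ndr than in WT cultures by rank of p. Cholesterol synthesis and xenobiotic genes were higher, and inflammation genes lower, by camera with the preset correlation, each at an adjusted p = 0.598 with an estimated correlation. edgeR called 0 of 15014 genes, with 438 at an unadjusted p under 0.05 (2.92%, below the chance share) and a smallest adjusted p of 0.987. That count was 774, with 2 edgeR calls, without Ndr peripheral 1219, 661 without Ndr peripheral 1224, and 280, 286 and 277 without Ndr peripheral 1220 and WT peripheral 1221 and 1223. limma-voom called 0 and DESeq2 called 10, of which 5 were higher and 5 lower. By unadjusted rank, Rgs16 averaged 79.2 ± 35.3 CPM in WT and 8.54 ± 1.01 CPM in Ndr peripheral cultures (n = 3 each; log2 -3.21, SE 0.645, edgeR adjusted p = 0.987). Slpi (ENSMUSG00000017002) averaged 27.4 ± 9.13 and 5.24 ± 2.81 CPM (log2 -2.38), Ntn1 (ENSMUSG00000020902) 73.2 ± 71.6 and 6.78 ± 4.65 CPM (log2 -3.43), and St3gal6 (ENSMUSG00000022747), a sialyltransferase gene, 15.6 ± 3.67 and 48.2 ± 24.8 CPM (log2 1.63). Chpt1, Amer2 and Rassf4 were lower (log2 -1.63, -2.86 and -3.40) and Tm7sf2, Cmtm7 and Cbr1 higher (log2 0.95, 1.23 and 0.94) in Ndr cultures. Of the 10 genes, Rgs16, Slpi, Ntn1 and Rassf4 passed in DESeq2. Tm7sf2, a sterol reductase gene (31.5 ± 3.23 and 60.7 ± 16.2 CPM), passed in edgeR when adjusted over the list alone, as did Wt1.

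camera called 8 lists in peripheral organoids, 7 of them at an adjusted p = 0.598 and proliferation at an adjusted p = 0.744 with an estimated correlation, and 3 stayed called when each library was left out in turn. All 24 cholesterol synthesis genes were higher in Ndr cultures, with a median of 0.52 (camera adjusted p = 1.8e-09), Hmgcs1 at 343 ± 96.4 CPM in WT and 447 ± 21.9 CPM in Ndr. With derivation date as a factor the medians had the other sign for cholesterol_synthesis (-0.18), inflammation (0.081), proliferation (-0.9955), tgfb_emt (0.088) and igf_insulin (0.13). In that fit the genotype difference averaged over both regions rests on mice 1224 and 1225 alone, which share a date. Xenobiotic and antioxidant genes had a median of 0.67, with 22 of 28 positive, and inflammation genes a median of -0.52, with 28 of 38 negative (camera adjusted p = 3.79e-06 for each). Gpx2 averaged 222 ± 71.5 and 509 ± 434 CPM, and Cp 3820 ± 1690 and 1250 ± 510 CPM. Proliferation genes (median 0.35, camera adjusted p = 0.00676), TGF-beta and mesenchymal genes (-0.18, 0.000821), basement membrane genes (-0.05, 0.00418) and IGF and insulin genes (-0.33, 0.00951) were not called without Ndr peripheral 1220 (0.839, 0.743, 0.766 and 0.766), where their medians changed sign: -0.031 for proliferation, 0.045 for tgfb_emt, 0.25 for basement_membrane_ecm and 0.016 for igf_insulin. Without a change of sign, the call was also lost for proliferation and IGF and insulin genes without WT peripheral 1221 (0.0762 and 0.0693) and for basement membrane genes without WT peripheral 1225 (0.0627). Unfolded protein response genes (-0.26, camera adjusted p = 0.00951) were not called without Ndr peripheral 1219 (0.295) or WT peripheral 1223 (0.095). Genotype effects in hilar and in peripheral organoids correlated at r = 0.107 and rho = -0.00635 across the 15014 genes, which are not independent replicates, and r ran from -0.184 to 0.471 in the other splits of the 6 mice.

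The region comparison asks whether ducts of the hilum and of the periphery keep different expression in culture. In WT organoids, the matricellular gene Smoc1 had higher values in hilar cultures, and Chpt1 and the enolase gene Eno2 lower values, by rank of p. Mitochondrially encoded and glycolysis genes were lower in hilar cultures by camera with the preset correlation, each at an adjusted p = 0.499 with an estimated correlation. edgeR, limma-voom and DESeq2 each called 0 genes, with 76 of 15014 genes at an unadjusted p under 0.05 in edgeR, or 0.506%. That count was 373, 204 and 191 without WT hilar 1221, 1223 and 1225, and 42 and 116 without WT peripheral 1221 and 1223. By unadjusted rank, Smoc1 (ENSMUSG00000021136) averaged 20.9 ± 10.7 CPM in hilar and 2.7 ± 0.974 CPM in peripheral WT cultures (n = 3 each; log2 2.95, SE 0.816, edgeR adjusted p = 1). Chpt1 (ENSMUSG00000060002) averaged 28.5 ± 5.85 and 67.3 ± 37.4 CPM (log2 -1.24), Eno2 (ENSMUSG00000004267) 2.46 ± 1.51 and 12.8 ± 8.79 CPM (log2 -2.40), and Pgap1 (ENSMUSG00000073678) 229 ± 61.8 and 441 ± 68.2 CPM (log2 -0.95). Lipo3, Aste1 and Hspb8 were higher (log2 1.43, 0.86 and 1.38) and Cln6 and Tmem164 lower (log2 -0.69 and -0.57) in hilar cultures. The mucin gene Muc5b (log2 -4.76, SE 1.79) reached 44.8 CPM in peripheral culture 1221 and at most 3.07 CPM elsewhere in WT cultures.

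camera called 7 lists in the WT region comparison, at adjusted p of 0.499 or 0.501 with an estimated correlation, and mitochondrially encoded genes stayed called when each library was left out in turn. All 13 of these were lower in hilar cultures, with a median of -1.38 (camera adjusted p = 6e-13), mt-Co3 at 894 ± 161 and 1860 ± 565 CPM. All 29 hypoxia and glycolysis genes were lower too (median -0.47, camera adjusted p = 1.78e-08), but not called without WT hilar 1221 (0.133). Notch components were lower (median -0.24, 24 of 30 negative, camera adjusted p = 0.00483), Adam10 at 231 ± 22.6 and 292 ± 24.7 CPM, and were not called without WT hilar 1223 (0.193) or 1225 (0.251). TGF-beta and mesenchymal genes (-0.37, camera adjusted p = 0.000454), basement membrane genes (-0.28, 0.00073), IGF and insulin genes (-0.31, 0.0126) and unfolded protein response genes (0.34, 0.000454) were not called without WT hilar 1225 (0.149), WT peripheral 1225 (0.053), WT hilar 1223 (0.286) and WT hilar 1225 (0.156), in that order. The IGF and insulin list was also lost without WT hilar 1225 (0.18) or either of WT peripheral 1221 (0.0551) and 1223 (0.0559), and the unfolded protein list without WT hilar 1223 (0.0623) or WT peripheral 1225 (0.0646). With the mouse as a block, camera also called the fibroblast and stellate genes lower in hilar cultures (adjusted p = 0.0284, and adjusted p = 0.604 with an estimated correlation).

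In Ndr organoids, the Notch ligand gene Jag2, the Notch feedback gene Nrarp and the cyclin gene Ccnd1 had lower values in hilar than in peripheral cultures. They passed in edgeR only when adjusted over the list alone, at an edgeR adjusted p = 0.418 over all genes. camera called neither the Notch component nor the Notch target list there. Proliferation, cholesterol synthesis and glycolysis genes were lower by camera with the preset correlation, each at an adjusted p = 0.706 with an estimated correlation. edgeR called 0 of 15014 genes, with 1548 at an unadjusted p under 0.05 (10.3%) and a smallest adjusted p of 0.418. limma-voom called 0 and DESeq2 called 79, of which 43 were higher and 36 lower in hilar cultures. Leaving out Ndr peripheral 1219 gave 7 edgeR calls, and without Ndr hilar 1220 the count at an unadjusted p under 0.05 was 818. By unadjusted rank, the noncoding RNA AU020206 (ENSMUSG00000097415) averaged 2.24 ± 0.439 CPM in hilar and 11.1 ± 2.72 CPM in peripheral Ndr cultures (n = 3 each; log2 -2.31, SE 0.43, edgeR adjusted p = 0.418). The carboxylesterase gene Ces2g (ENSMUSG00000031877) averaged 5.8 ± 1.2 and 20.2 ± 8.3 CPM (log2 -1.79), Dock11 16 ± 6.6 and 52.8 ± 6.19 CPM (log2 -1.72), Rbm38 (ENSMUSG00000027510) 8.7 ± 0.869 and 17.9 ± 2.09 CPM (log2 -1.04), and Jag2 (ENSMUSG00000002799) 24.8 ± 6.99 and 72.6 ± 9.75 CPM (log2 -1.55, SE 0.322). Syne4 (log2 3.21), the ciliary kinase gene Mak (2.48) and the imprinted noncoding RNA Rian (4.97) were higher, and Inf2 (-1.55) and Coro1c (-0.91) lower in hilar cultures. All 10 passed in DESeq2.

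Members of several lists passed in edgeR for the Ndr region comparison when adjusted over the list alone. Beside Jag2, these were Ccnd1 (477 ± 104 CPM in hilar and 1200 ± 107 CPM in peripheral cultures) and Nrarp (1.75 ± 0.888 and 5.94 ± 1.97 CPM) among Notch targets, Ddit4l (195 ± 79.2 and 53 ± 10.2 CPM), the laminin receptor gene Itga6 (61.2 ± 26 and 218 ± 82.9 CPM), Col18a1 (135 ± 41.8 and 342 ± 129 CPM) and Cdhr5 (0.536 ± 0.255 and 17.6 ± 15.9 CPM). The intestinal genes Cdx2 (4.74 ± 4.26 and 39.9 ± 41.3 CPM) and Vil1 (111 ± 29.9 and 212 ± 80.8 CPM) passed as well, with Cdx2 at 85.5 CPM in Ndr peripheral 1220. With the mouse as a block, Jag2 (0.0253), Ccnd1 and Nrarp (0.0277 each) and Itga6 (0.014) still passed, while Ddit4l (0.151), Col18a1 (0.068), Cdhr5 (0.26), Cdx2 and Vil1 (0.137 each) did not. The block added Fgg, Alb, Ambp, Trf and Ttr of the hepatocyte list, Postn, and 14 cholesterol synthesis genes from Fdps, Hmgcs1 and Hsd17b7 (0.0238 each) to Cyp51 and Dhcr7 (0.0469 each). camera called 7 lists, at adjusted p of 0.706 or 0.726 with an estimated correlation. All 44 proliferation genes (median -1.75, camera adjusted p = 1.39e-20), all 24 cholesterol synthesis genes (-1.01, 2.69e-13), 28 of 29 hypoxia and glycolysis genes (-1.05, 1.63e-10) and, in the other direction, 30 of 37 primary cilium genes (0.41, 7.06e-06) stayed called when each library was left out in turn, with a hypoxia_glycolysis median of -0.65 without Ndr peripheral 1224. Top2a averaged 67.1 ± 19.7 and 257 ± 57.3 CPM, Hmgcs1 197 ± 8.4 and 447 ± 21.9 CPM, and Pkm 918 ± 208 and 2350 ± 621 CPM. Unfolded protein response genes (0.40, camera adjusted p = 0.0313), xenobiotic genes (-0.59, 0.0379) and fibroblast and stellate genes (0.57, 0.0472) were called with all libraries but not without Ndr hilar 1224 (0.443), Ndr hilar 1220 (0.246) and Ndr peripheral 1220 (0.242), in that order. The unfolded protein list was also lost without Ndr hilar 1219 (0.109) or Ndr peripheral 1219 (0.269), the xenobiotic list without Ndr hilar 1219 (0.0572), Ndr peripheral 1219 (0.102) or 1220 (0.0546), and the fibroblast list without Ndr hilar 1220 (0.115). With the mouse as a block, camera also called the hepatocyte genes higher in hilar cultures (median 0.59, adjusted p = 0.0193, and adjusted p = 0.734 with an estimated correlation).

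Over both genotypes, Jag2, AU020206 and the ciliary gene Mak were among the genes with the smallest p between regions. Jag2 averaged 35.6 ± 13.8 CPM in hilar and 45.2 ± 13.4 CPM in peripheral WT cultures, and its log2 difference over both genotypes was -0.95 (SE 0.224, edgeR adjusted p = 0.786), which passed when adjusted over the list alone (0.0409) but not with the mouse as a block (0.0506). edgeR called 0 of 15014 genes, with 911 at an unadjusted p under 0.05 (6.07%) and a smallest adjusted p of 0.786. That count was 1617 without WT hilar 1225 and 597 without Ndr peripheral 1224. limma-voom called 0 and DESeq2 called 2. By unadjusted rank, AU020206 (log2 -1.33), Mak (1.63), the brush border myosin gene Myo7b (-4.59), Dock11 (-1.03), Jag2, Nrn1 (-6.88), Ces2g (-0.98), Itpk1 (-1.11), Zfp983 (0.85) and Add2 (-3.29) came first among named genes of at least 5 CPM. Of these, Myo7b passed in DESeq2, and it reached 68.7 CPM in Ndr peripheral 1224, where Nrn1 reached 91.2 CPM. camera called 8 lists, each at an adjusted p = 0.503 with an estimated correlation, of which proliferation (median -0.70, camera adjusted p = 4.67e-17), hypoxia and glycolysis (-0.79, 2.23e-15), cholesterol synthesis (-0.34, 4.94e-09), mitochondrially encoded (-1.10, 2.87e-06), unfolded protein response (0.32, 0.000146) and primary cilium genes (0.25, 0.00029) stayed called when each library was left out in turn. Their medians were smaller for proliferation without Ndr peripheral 1220 (-0.39), cholesterol_synthesis without WT hilar 1221 (-0.20), mitochondrial_encoded without Ndr peripheral 1219 (-0.41) and primary_cilium without Ndr hilar 1220 (0.12). Hspa5, a chaperone of the endoplasmic reticulum, averaged 1560 ± 483 and 1120 ± 162 CPM in WT and 1270 ± 381 and 877 ± 141 CPM in Ndr hilar and peripheral cultures. Basement membrane genes (-0.32, camera adjusted p = 0.00241) were not called without Ndr hilar 1219 (0.13) or Ndr peripheral 1219 (0.395). Xenobiotic genes (-0.22, 0.0357) were lost without any of 6 libraries, at camera adjusted p from 0.0548 to 0.179.

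The interaction asks whether the genotype difference depends on the region. Chpt1, which makes phosphatidylcholine, and Rian were higher in hilar than in peripheral cultures of each Ndr mouse and lower in each WT mouse, while Rbm38 and Dffa went the other way. edgeR called 0 of 15014 genes, with 451 at an unadjusted p under 0.05 (3%), and a smallest adjusted p of 0.994. That count was 1366 and 189 without WT hilar 1221 and 1225, 1025 and 202 without Ndr hilar 1219 and 1220, 774 and 294 without Ndr peripheral 1219 and 1220, and 292 and 190 without WT peripheral 1221 and 1223. limma-voom called 0, and DESeq2 called 4, which were Chpt1, Rbm38, Smoc1 and Rian. By unadjusted rank, Chpt1 had 28.5 ± 5.85 CPM in WT hilar, 67.3 ± 37.4 CPM in WT peripheral, 77 ± 29.7 CPM in Ndr hilar and 21.7 ± 4.51 CPM in Ndr peripheral cultures (n = 3 each; interaction log2 3.07, SE 0.564, edgeR adjusted p = 0.994). Smoc1 (interaction log2 -5.43, SE 1.16) averaged 20.9 ± 10.7, 2.7 ± 0.974, 1.69 ± 0.596 and 9.55 ± 9.59 CPM in the same order, and the alkaline phosphatase gene Alpl (ENSMUSG00000028766; interaction log2 6.45, SE 1.8) 2.61 ± 1.84, 3.4 ± 2.13, 64.9 ± 90.7 and 0.922 ± 1.02 CPM. Rbm38 (-1.41), Rian (6.04), Sgsm1 (-2.93), Slc52a3 (-1.57), Ces2g (-1.63), Dffa (-0.97) and Eid1 (1.19) completed the 10 genes. camera called 6 lists, each at an adjusted p = 0.939 with an estimated correlation: proliferation (median -2.02, camera adjusted p = 3.33e-15), cholesterol synthesis (-1.11, 2.94e-12), primary cilium (0.45, 6.87e-05) and fibroblast and stellate genes (2.01, 0.00321), which stayed called when each library was left out in turn, and mitochondrially encoded (0.55, 0.0108) and hypoxia and glycolysis genes (-0.54, 0.0136). Without WT hilar 1225 the medians fell to -0.67 for proliferation and -0.47 for cholesterol_synthesis. The primary_cilium median was 0.27 without Ndr hilar 1220, that of other_fibroblast_stellate 1.17 without WT peripheral 1223, and that of mitochondrial_encoded 1.86 without Ndr peripheral 1219. Few fibroblast and stellate genes were tested. Their mean differed between hilar and peripheral cultures by 4.08 in Ndr mouse 1220, 0.65 in 1219 and -0.137 in 1224. In WT mice 1221, 1225 and 1223 it differed by 0.337, -1.17 and -1.76. Hypoxia and glycolysis genes were not called without Ndr hilar 1220 (0.643), Ndr peripheral 1224 (0.633), WT hilar 1225 (0.467) or WT peripheral 1223 (0.453). Mitochondrially encoded genes were not called without Ndr hilar 1224 (0.165), Ndr peripheral 1220 (0.411) or 1224 (0.127), WT hilar 1223 (0.0521) or WT peripheral 1221 (0.128). With the mouse as a block, camera also called the hepatocyte genes (median 0.80, adjusted p = 0.00465, and adjusted p = 0.962 with an estimated correlation), and Fgg, Ambp (0.0397 each) and Trf (0.0482) passed when adjusted over the list alone.

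Other lists were not called by camera between genotypes in the mouse totals with all 6 mice. There, median log2 differences between genotypes and camera adjusted p were -0.08 and 0.549 for Notch components, 0.12 and 0.315 for Notch targets, -0.10 and 0.629 for biliary transport, -0.29 and 0.873 for hepatocyte genes, -0.05 and 0.434 for Wnt and stem genes, and -0.15 and 0.0509 for YAP targets. They were -0.04 and 0.42 for junction and polarity genes, -0.20 and 0.138 for interferon genes, 0.01 and 0.951 for immediate early and heat shock genes, and -0.68 and 0.549 for the 5 immune genes. The mean had the other sign than the median for biliary transport (0.04). With 1 mouse left out, camera did call some lists that it did not call with all mice. Proliferation genes were then lower in Ndr mice without Ndr 1220, WT 1221 or WT 1223 (camera adjusted p of 0.000137, 0.00158 and 0.000534). They were higher without WT 1225 (0.000319), as were cholesterol synthesis genes (2.8e-12). Among the most abundant members, the Notch target Id2 averaged 412 ± 94.6 CPM in WT and 587 ± 101 CPM in Ndr mice, and the chloride cotransporter gene Slc12a2 779 ± 188 and 472 ± 35.5 CPM (log2 -0.72, edgeR adjusted p = 0.798). Few members of some other lists were tested: 3 endothelial genes (median 0.36, Egfl7 at 9.36 ± 1.51 and 12 ± 2.26 CPM), 4 mesothelial and neural genes (0.49, Msln at 299 ± 247 and 339 ± 83.2 CPM), 4 gut and pancreas genes (0.51, Vil1 at 166 ± 25.1 and 162 ± 32.6 CPM), 4 sex-linked genes (0.11) and 6 fibroblast and stellate genes (0.99, camera adjusted p = 0.0711, Gas6 at 532 ± 335 and 770 ± 259 CPM). Some markers of other cell types were abundant. Beside Trf, the hepatocyte-list gene Gc averaged 1130 ± 702 CPM in WT and 901 ± 535 CPM in Ndr mice. The immune-list gene Cd14 averaged 486 ± 223 and 714 ± 158 CPM. Among other lists without a call, median, mean and camera direction differed in sign for mitochondrially encoded genes in peripheral organoids (median 0.28, camera downward), for proliferation genes between WT regions (0.34, camera downward) and for hepatocyte genes in hilar organoids (-0.23, camera upward). For IGF and insulin genes between Ndr regions the median was -0.28 and the mean 0.25.

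The deposited normalized values gave other counts of genes between genotypes than the raw counts did. On the whole counts recovered from that table, edgeR called 1514 genes in hilar organoids, 126 in peripheral organoids and 6753 in the mouse totals, where it called 0 on the raw counts. The genes called in the mouse totals had the same sign on the raw counts in 75.4% of cases, and 9.41% of them had an unadjusted p under 0.05 there. Their median SE was 0.0897 on the recovered counts and 0.24 on the raw counts. Counts simulated with no effect of genotype, mouse or date and then adjusted with ComBat-seq in the same way gave edgeR calls for 49% to 50% of genes in the mouse totals, 5.17% to 5.8% in hilar and 5.66% to 6.61% in peripheral organoids. Before that adjustment the same simulated counts gave 0 or 1 call.

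**Figure D4:**
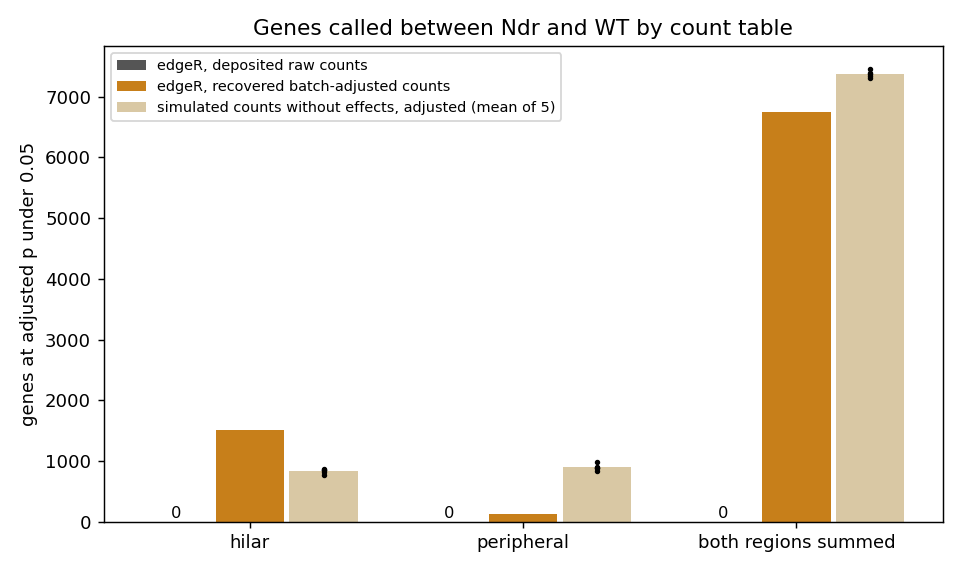
Genes called between Ndr and WT organoids by edgeR at an adjusted p under 0.05 on the raw counts, on the whole counts recovered from the normalized table and on simulated counts without effects after the same adjustment. Bars start at 0 and points are the 5 simulated draws; in the mouse totals the calls are 0, 6753 and between 7316 and 7463.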

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

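The test with derivation date as a factor on the raw counts, both tests of the proliferation list and the test of the shared animal were chosen only after the result was seen.

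In 6 gene lists the genotype difference depended on the region by camera with the preset correlation. The interaction medians were -2.02 for proliferation, 0.45 for primary cilium, -1.11 for cholesterol synthesis, -0.54 for hypoxia and glycolysis, 0.55 for mitochondrially encoded and 2.01 for fibroblast and stellate genes, each with an adjusted p = 0.939 with an estimated correlation. Without WT hilar 1225 the medians fell to -0.67 for proliferation and -0.47 for cholesterol_synthesis. Of the 10 genes named for the interaction, 4 went one way between regions in each Ndr mouse and the other way in each WT mouse: Chpt1 (3.07), Rbm38 (-1.41), Rian (6.04) and Dffa (-0.97). As a set chosen by these directions they were not tested. Of the 15014 genes, 198 or 1.32% do this, where chance gives 3.12%. None of the gene lists did so in its mean per culture.

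Genes were called between genotypes in large numbers only on the batch-adjusted counts. Counts simulated without any effect and adjusted the same way gave calls for at least 49% of genes in the mouse totals, so the adjustment alone may produce such calls there. In hilar organoids the simulated counts gave 768 to 860 calls against 1514 on the recovered counts, and in peripheral organoids 841 to 981 against 126, so the source of the calls within each region stays open. For the mouse totals, with other splits of the 6 mice as the kept group, 3 of the 7 that could be fitted reached at least 0.5 of the 6748 calls of the real genotypes, the highest at 7189. These 3 splits, at 5522, 7189 and 5162 calls, were those in which 1 date held both groups, as for the real genotypes. In the other fitted splits, both of the dates that mice shared held both groups. In hilar organoids 1 of the 7 reached that share, at 2773 against 1524, and in peripheral organoids 3 did, the highest at 259 against 128. The splits with 1 such date gave 69, 181 and 318 calls in hilar organoids. With date as a factor on the raw counts edgeR called 7 genes, in a fit with 1 residual degree of freedom. A genotype difference hidden by derivation date stays open, since 1 date held both genotypes.

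Proliferation genes were lower in Ndr than in WT hilar organoids, at a median of -1.71. Without WT hilar culture 1225 the median was -0.306, and without 1221 or 1223 it was -2.09 or -2.17, so that 1 culture with high cell cycle expression may account for most of the difference. The Ndr culture had the lower list mean in 7 of the 9 pairs of 1 Ndr and 1 WT hilar culture. Genotype stays open as a part of the difference.

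Cultures of the same mouse were not more alike than cultures of different mice. The mean correlation of the 6 real pairs was 0.0345, and 16 of the 36 ways to pair hilar with peripheral cultures within genotypes gave one as high, up to 0.27. An effect of the shared animal stays open with so few mice.

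Splits of 3 samples against 3 are too few for a share under 0.05. For genes at an unadjusted p under 0.05 in edgeR, the real count and the highest other were 982 and 3983 for genotype in hilar organoids (5 of 10 splits as large), 438 and 714 in peripheral organoids (5 of 10), 76 and 1624 for region in WT (10 of 10), 1548 and 3167 for region in Ndr (3 of 10), 451 and 3708 for the interaction (7 of 10), and 834 and 1953 for genotype in the mouse totals (5 of 10). Most region splits within a genotype kept both cultures of a mouse on the same side. Among the other splits that parted all 3 pairs, the highest counts were 472 in WT and 3167 in Ndr. For region over both genotypes, 13 of 32 exchanges within mice gave as many as the real 911, up to 3345, so chance is not excluded. Splits with several times the real count, in hilar genotype, WT region, the interaction and region over both genotypes, point to a structure of the samples, whose source was not tested.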

How the results depend on the processing

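The recovered batch-adjusted counts, the ComBat-seq rerun, the 12 libraries as independent samples, the fit without mitochondrial genes and the leaving out of libraries in the list tests were chosen only after the data were seen. Where a value moved, the cause was not tested.

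edgeR called 0 genes in all 7 comparisons. DESeq2 called 44 for genotype in hilar organoids, 10 in peripheral organoids, 79 for region in Ndr, 4 for the interaction, 2 for region over both genotypes and 124 for genotype in the mouse totals. limma-trend on the deposited normalized values called 1480, 92, 7, 2, 3 and 6307 in the same order. On the recovered counts edgeR called 1514 and 126 for genotype in hilar and peripheral organoids, 5 and 30 for region in WT and Ndr, and 6753 in the mouse totals. DESeq2 on them called 2510, 399, 32 and 288 in that order, 30 for the interaction, 238 for region over both genotypes and 6130 in the mouse totals. edgeR on the ComBat-seq rerun called 1524 in hilar organoids, 128 in peripheral organoids and 6748 in the mouse totals. In the mouse totals, no low-count filter gave 5, derivation date as a factor 7, and the 12 libraries as independent samples 4 in edgeR and 117 in DESeq2.

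Leaving out 1 library gave edgeR counts from 0 to 2 for genotype in peripheral organoids (2 without Ndr peripheral 1219), 0 to 7 for region in Ndr (7 without Ndr peripheral 1219) and 0 to 4 in the mouse totals (4 without Ndr 1219). In the other 4 comparisons each library left out gave 0. With the replicate block edgeR called 0 genes, with 72, 1270, 413 and 759 at an unadjusted p under 0.05 for region in WT, in Ndr, the interaction and region over both genotypes.

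Of the list calls by camera, 0 were left in each of the 7 comparisons with an estimated correlation and by fry. fry for either direction called 0 in 6 comparisons and 3 in the mouse totals, and the replicate block with an estimated correlation 0 in the 4 comparisons with region. Beside the lists and list members named in the report, the block changed no list call by camera. With 1 library left out, camera called 5 to 12 lists in peripheral organoids (5 without Ndr peripheral 1220) and 4 to 10 in the mouse totals (10 without Ndr 1224, 9 without WT 1221 or WT 1223), and 23 of the 48 calls held with each library left out. Lists without a call could also gain one in either direction. Between WT regions, proliferation genes were lower in hilar cultures without WT hilar 1225 (camera adjusted p = 2.1e-39) and higher without WT hilar 1223 (1.87e-05). Cholesterol synthesis genes did the same (1.74e-12 and 0.00802). A kept call at the preset correlation therefore gives little support.

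Of 1041 medians of called lists under alternatives, 21 changed sign, in 8 pairs of a list and a comparison. In peripheral organoids, limma-trend on the normalized values, derivation date as a factor and edgeR on the recovered counts gave 0.061, 0.13 and 0.028 for igf_insulin, -1.19, -0.9955 and -1.25 for proliferation (-1.24 in DESeq2) and -0.21, -0.18 and -0.24 for cholesterol_synthesis (-0.23 in DESeq2). limma-trend and date gave 0.017 and 0.088 for tgfb_emt and 0.0096 and 0.081 for inflammation. With date as a factor, the genotype difference averaged over both regions rests on the 1 date that held both genotypes. With 1 library left out the medians ran from -0.49 to 0.016 for igf_insulin, -0.031 to 0.52 for proliferation, -0.45 to 0.045 for tgfb_emt and -0.52 to 0.25 for basement_membrane_ecm, each changing sign without Ndr peripheral 1220. In hilar organoids cholesterol_synthesis ran from -0.85 to 0.024, changing sign without WT hilar 1225. In the mouse totals limma-trend gave 0.030 for inflammation and 0.25 for Jag1.

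Of 2418 values of named genes under alternatives, 2406 kept their direction and 251 passed the adjusted threshold of the alternative's own test. Most of these genes were chosen by p in the main fit on the same libraries, so a kept direction gives little support.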

Other observations

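The share of mitochondrially encoded counts ran from 0.557% in WT hilar 1225 to 4.25% in Ndr peripheral 1219. The identifier ENSMUSG00000119584, without a symbol here, took from 0.102% to 0.9% of the counts of a library and was the most abundant in WT hilar 1225. Clu was the most abundant in 9 libraries and Eef1a1 in 2.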
